A study of Homo sapiens with 15 samples.

How the data were processed

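RNA from 15 cultures of HBE cells was hybridised to one-colour (Cy3) Agilent arrays of 61184 spots, 3 arrays for each of 5 groups. Per the labels, ribosomal RNA was removed and the rest was amplified and labelled with random primers along the whole transcript. The deposited scanner files hold Cy3 intensities made by Agilent Feature Extraction 11.0.1.1 with protocol GE1_1100_Jul11, per the file headers, which name build GRCh37. The processed intensity had been background-subtracted and detrended within each array by that program, with low values replaced by a surrogate, and not scaled between arrays. The deposited value table holds log2 values of 58944 probes that rank each array's probes as the scanner signals do (rank correlation 1) and share 1 distribution, with medians of 2.78 to 2.82, as quantile normalization gives; which tool made them and what was done at the low end are not stated. That table lacks the 20 reference probes and 1 other probe. The labels give the PBS group a dose of 100 µg/ml, which was not used, and give the cultures no shared numbers, donors or batches.

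Spots that Feature Extraction had marked as non-uniform and all control spots were left out, and the log2 processed signals of the spots of 1 probe were averaged. A probe counted as above background where over 0.5 of its spots were well above background. Between 13.9% and 23.4% of the array probes on each array were, so each array's log2 signals were set relative to its 75th percentile over the 7188 probes above background on all 15 arrays. Probes above background on at least 3 of the 15 arrays were tested, 14281 of the 58945 array probes and 20 reference probes (24.2%). Where a probe was not above background on every array of the dimmer group, its fold was given as at least N-fold, the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes above background and the probe's own.

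All 15 arrays were fitted in 1 model with a mean per group by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, 10 residual degrees of freedom). Every p is from limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05, and counts at 2-fold or more stand beside it. The moderated F test covered the 5 groups together. All 10 pairs of groups were computed. The p-values measure the spread between cultures whose independence the labels do not state. Errors are SD of 3 arrays for levels and SE of the fit for changes. Files were read with the R packages data.table (1.17.8) and jsonlite (2.0.0). The fit was tested on simulated data with 200 changed probes of 14244 in PM2.5 high against PBS. Without a slide difference it recovered 13.4%, 34.3% and 90.9% of changes of 0.5, 1 and 2 on the log2 scale and called 4 unchanged probes. With a simulated slide difference of SD 0.5 it called 2688 unchanged probes (19.1%), and 3 with the slide as a block, which recovered 0%, 8.96% and 42.4% of the changes.

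The groups, comparisons, tests, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. That rule names 12 stress and metabolism genes, the 6 largest separated rises and falls among named genes, and members of gene lists; without a table of genes it names 2 probes up and 2 down. No file given pairs the array's probes with genes, so the 12 genes, the gene list tests (camera and fry), the cell type markers and the split into coding and non-coding transcripts could not be run. The 20 reference probes carry accessions, all 20 of which matched a gene symbol in the reference table; 18 were tested, and the 6 largest separated rises and falls among them are named for each comparison, with other members where a group is described. DEP against PM2.5 high was singled out from the 10 pairs after the slides were known.

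The slide of each array was taken from the scan the files share. The alternatives fixed in advance were quantile normalization, median centring, normexp background correction (offset 50), no filter on dim probes, a filter on probes above background on all 15 arrays, no intensity trend, array weights, the slide as a block, only the 2 groups compared, the deposited value table, a 2-fold threshold and leaving out each array. The files hold no mean signal, so normexp used the median spot and median background signals. Alternatives added after the data were seen were slide 1 alone, slide 2 alone, the block with the filter on all 15 arrays, and the 75th percentile over all probes. Overlaps were set against independent lists of the same sizes and against 20 simulated sets of unchanged groups that share simulated control arrays. The changes of some reference genes are not reported here, nor their values under the alternatives, though the counts of reference genes include them.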

Results

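RNA levels were measured in HBE cells, a human bronchial epithelial cell line, after 24 h with one of 4 particle exposures or with PBS, the vehicle control. The exposures were aluminium oxide nanoparticles (Al2O3 NPs) at 100 µg/ml, fine particulate matter (PM2.5) at 100 µg/ml (low) or 500 µg/ml (high), and DEP at 50 µg/ml. Each of the 5 groups had 3 one-colour arrays, 15 in all, whose probes cover protein-coding and long non-coding transcripts. Between 13.9% and 23.4% of the array probes on each array were above background (8178 to 13820 probes). The group means of that percentage were 17.6 ± 2.0 for PBS, 17.1 ± 3.3 for Al2O3 NPs, 22.3 ± 1.7 for PM2.5 low, 21.1 ± 0.76 for PM2.5 high and 21.4 ± 1.0 for DEP (SD, n = 3 each). No spot was saturated, and the number of arrays limits the precision. All levels are given as log2 signal relative to the array's 75th percentile, so a negative level is a probe dimmer than that percentile.

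The files pair no gene with the array's main probes. Apart from control probes for GAPDH and PGK1, which were not tested, genes could be named only for 20 reference probes. Each reference probe was printed in 10 spots, and 18 of the 20 were bright enough to test. They include the cytoplasmic actins ACTB and ACTG1, the glycolytic enzyme GAPDH, the ribosomal proteins RPS18 and RPLP1, the mitochondrial proteins COX4I1 and MTX1, and the dynein light chain DYNLL1. The reference probes for PGK1 and RPL10 were above background on 1 and 0 arrays and were not tested. Beyond these genes, the probes with the largest separated changes are given by their identifiers.

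The arrays came from 2 slides. Slide 1 held the 3 PBS arrays, the 3 Al2O3 NPs arrays and PM2.5 low replicates 1 and 2. Slide 2 held PM2.5 low replicate 3 and all PM2.5 high and DEP arrays, so the comparisons of PM2.5 high and DEP with PBS crossed slides and only PM2.5 low joined them. The first principal component, with 36.9% of the variance, placed PBS and PM2.5 low replicates 1 and 2 between -48.6 and -39.8 and the PM2.5 high and DEP arrays between 33.6 and 66.6. PM2.5 low replicate 3 lay at 8.26 on it, away from the other two arrays of its group. The second component, with 20.7%, placed the Al2O3 NPs and DEP arrays at -46.0 to -5.84 and all PBS and PM2.5 arrays at 10.6 to 42.9. The number of probes called in each comparison is therefore given also from a fit with the slide as a block.

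**Figure D1:**
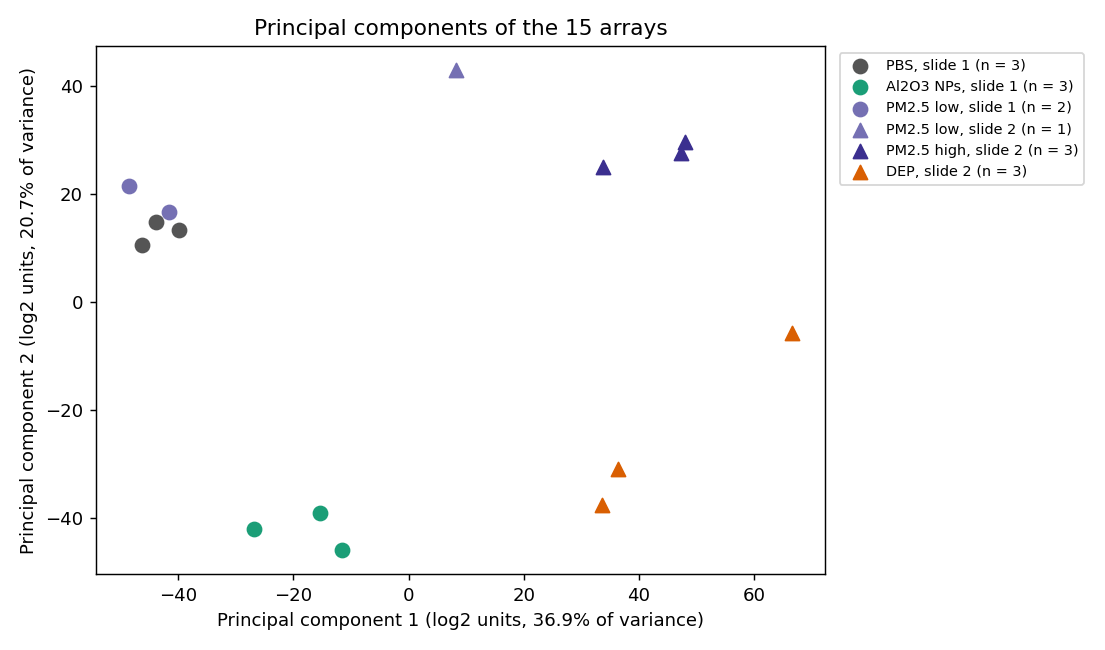
Scores of the 15 arrays on the first 2 principal components (36.9% and 20.7% of the variance, in log2 units). Each point is 1 array, coloured by group, with circles for slide 1 and triangles for slide 2; the first component parts the slides, with PM2.5 low replicate 3 at 8.26, and the second parts the Al2O3 NPs and DEP arrays from the others.

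Al2O3 NPs against PBS sets the nanoparticles against the vehicle, and all 6 arrays lay on slide 1. GAPDH RNA was 1.88-fold higher after Al2O3 NPs (log2 change 0.91, SE 0.11, adjusted p = 4.67e-05; level -1.28 ± 0.043 against -2.20 ± 0.075, SD, n = 3 each). DYNLL1, a light chain of the dynein motor, was 1.88-fold lower (-0.91, SE 0.092, adjusted p = 7.22e-06). The arginine methyltransferase PRMT1 (-0.55), ACTG1 (-0.54), the replacement histone H3-3A (-0.51), the cytochrome c oxidase subunit COX4I1 (-0.49) and the translation initiation factor subunit EIF3D (-0.48) fell too, with adjusted p from 7.80e-04 to 0.00658; without the filter on dim probes COX4I1 and EIF3D did not pass (adjusted p = 0.0992 and 0.0881). The other 11 of the 18 reference genes did not pass the test; adjusted over the list alone, 1 was higher and 8 were lower, and with the slide as a block also 1 and 8.

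Probe ASHGA5P031802 fell 10.7-fold after Al2O3 NPs (level -2.35 ± 0.076 against 1.08 ± 0.082, SD, n = 3 each, adjusted p = 2.77e-11), and ASHGA5P030215 was at least 11.5-fold lower, above background on 2 of the 3 Al2O3 NPs arrays (level -4.61 ± 1.76, SD). ASHGA5P029896 was at least 2.84-fold higher and ASHGA5P015333 at least 1.76-fold higher, both above background on the 3 Al2O3 NPs arrays and on no PBS array. By limma's moderated test, 2244 of 14281 probes (15.7%) passed an adjusted p of 0.05, of which 709 were higher and 1535 lower. At 2-fold or more, 161 were higher and 695 lower. The fit with the slide as a block gave 1220 and 1887, and slide 1 alone 2009 and 2194. The percentage of calls that were higher, 31.6%, was 42.6% with median centring and 52.4% with normexp background correction.

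PM2.5 low against PBS sets the lower particulate dose against the vehicle. GAPDH was 1.73-fold lower after PM2.5 low (log2 change -0.79, SE 0.11, adjusted p = 0.00323; level -2.99 ± 0.15, SD, n = 3), the opposite direction to Al2O3 NPs. ACTG1 was 1.48-fold lower (-0.57, SE 0.091, adjusted p = 0.00726). Both falls were present with the slide as a block, at -0.88 for GAPDH (adjusted p = 3.98e-04) and -0.60 for ACTG1 (adjusted p = 0.00193), and on slide 1 alone, where 2 PM2.5 arrays met 3 PBS arrays (adjusted p = 6.50e-04 and 0.00172). The other 16 reference genes did not pass the test, and adjusted over the list alone the counts were the same, 0 higher and 2 lower. Fitted on the 6 arrays of the 2 groups alone, neither fall passed (adjusted p = 0.128 and 0.135).

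ASHGA5P030759 was at least 2.12-fold lower after PM2.5 low and above background on all 3 PBS arrays and on no PM2.5 low array. ASHGA5P008393 was at least 2.69-fold lower, above background on 1 of the 3 PM2.5 low arrays. ASHGA5P044390 was at least 1.30-fold higher and ASHGA5P044142 at least 1.18-fold higher, the second without passing with the slide as a block (adjusted p = 0.0819) or with quantile normalization (adjusted p = 0.0766), no filter (adjusted p = 0.0701), normexp (adjusted p = 0.0711) or the deposited values (adjusted p = 0.0753). With only the groups compared none of these 4 passed (adjusted p = 0.0594, 0.107, 0.126 and 0.117). In PM2.5 low vs PBS, 307 probes were higher and 53 lower (360, 2.52% of those tested), 79 and 11 at 2-fold or more. The block gave 301 higher and 329 lower, with 299 of the 360 called in the same direction, and slide 1 alone 436 and 496. Only the groups compared gave 6 and 0, and array weights 1549 and 1038. Leaving out each array in turn gave 121 to 631 calls, the most without PM2.5 low replicate 3. The percentage higher, 85.3% by the main scaling, was 54.5% with the 75th percentile taken over all probes.

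PM2.5 high against PBS sets the higher dose against the vehicle, with PBS on slide 1 and PM2.5 high on slide 2, so dose and slide changed together. Of the 18 reference genes, 16 were higher after PM2.5 high relative to the array's 75th percentile. The log2 signal of that percentile was 10.10 to 10.18 in PBS and 9.24 to 9.31 in PM2.5 high. A lower percentile raises the relative level of a probe whose signal is unchanged, so the scaling may make up much of these rises. GRM4, a glutamate receptor, was at least 1.83-fold higher (above background on 2 of the 3 PBS arrays; log2 change 0.91, SE 0.21, adjusted p = 0.00424). The ribosome-associated scaffold RACK1 (0.86), ACTB (0.85), GAPDH (0.80), RPS18 (0.80) and ODC1, which catalyses the first step of polyamine synthesis (0.79), followed, and the other 10 lay between 0.48 and 0.76. With quantile normalization, where the brightest probes are tied across arrays, RACK1, ACTB, RPLP1, PFN1 and RPS18 did not pass (0.15, 0.04, 0.02, 0.01 and 0.00), and with the percentile over all probes H3-3A, COX4I1 and MTX1 did not (0.13, 0.10 and 0.13). ACTG1 (-0.20, adjusted p = 0.0862) and DYNLL1 (0.11, adjusted p = 0.372) did not pass; with the 75th percentile taken over all probes both were lower (-0.58, adjusted p = 0.00137, and -0.27, adjusted p = 0.0492). ACTG1 was also lower with median centring (-0.30, adjusted p = 0.0122), normexp (-0.22, adjusted p = 0.0436), array weights (-0.20, adjusted p = 0.0134) and only the groups compared (-0.20, adjusted p = 0.0183). Adjusted over the list alone, 16 were higher and 1 lower.

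The median change of all tested probes after PM2.5 high was 0.26 on the log2 scale, against 0.06 with quantile normalization and -0.12 with the percentile over all probes. Relative to that median, GRM4 was higher by 0.65, RACK1 by 0.60, ACTB by 0.59 and GAPDH by 0.54. With the slide as a block, only ODC1 of the 18 passed (0.54, adjusted p = 0.0202), while GAPDH was at 0.53 (adjusted p = 0.0705). GRM4 was then at 0.22 (adjusted p = 0.691), RACK1 at 0.44 (0.173), ACTB at 0.33 (0.313) and RPS18 at 0.26 (0.398). GRM4 was dim, at -4.58 to -4.32 in PBS. Of the control probes near that level, (+)E1A_r60_a22, DCP_22_0 and DCP_22_2 were higher than in PBS by 1.006, 0.93 and 0.98. Mouse-GAPDH_5 and Rat-GAPDH_3 differed by -0.18 and -0.35. On PM2.5 low replicate 3, on slide 2, GRM4 lay at -3.74, against -4.49 and -4.36 on replicates 1 and 2. A slide or scaling difference may therefore make up part of its rise.

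Of the other probes, ASHGA5P058274 was at least 2.34-fold higher after PM2.5 high and ASHGA5P032351 at least 1.93-fold higher. ASHGA5P013218 was at least 6.99-fold lower and ASHGA5P058414 at least 1.76-fold lower. ASHGA5P058274 passed with the slide as a block (adjusted p = 0.0154). ASHGA5P032351 did not (adjusted p = 0.150), with a log2 change of 3.07 against 3.205 without the block and an SE of 1.22 against 0.66. Nor did ASHGA5P013218 (adjusted p = 0.768), whose change was -1.26 against -4.76 (SE 2.17 against 1.31). ASHGA5P058414 did not pass either (adjusted p = 0.357), with a change of -0.90 against -2.99 (SE 0.56 against 0.48). Each of the 4 was above background on no array of one group, so the size of its change is not fixed. In all, 4435 probes were higher and 1474 lower (5909, 41.4% of those tested), 2068 and 624 at 2-fold or more. The block left 604 higher and 493 lower, and 537 of the 5909 were called in the same direction. The percentage higher, 75.1%, was 55.5% with quantile normalization, 54.9% in the deposited value table, 90.3% with normexp and 37.9% with the percentile over all probes.

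DEP against PBS also crossed slides. ACTG1 was 2.58-fold lower after DEP (log2 change -1.37, SE 0.091, adjusted p = 1.87e-07; level -0.84 ± 0.11 against 0.53 ± 0.064, SD, n = 3 each), and DYNLL1 was 2.11-fold lower (-1.08, SE 0.092, adjusted p = 1.74e-06). MTX1, of the mitochondrial outer membrane, fell by 0.58 and PRMT1 fell by 0.50, and H3-3A was lower by a smaller amount (-0.27, adjusted p = 0.0404; not past the threshold with quantile normalization, adjusted p = 0.187, no intensity trend, 0.0719, only the groups compared, 0.0885, or no filter, 0.265). These 5 genes were lower with the slide as a block too, ACTG1 at -1.47 (adjusted p = 3.26e-05), DYNLL1 at -1.16 (adjusted p = 2.01e-04), MTX1 at -0.70, PRMT1 at -0.76 and H3-3A at -0.48, and COX4I1 joined them (-0.49, adjusted p = 0.0444).

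GRM4 was at least 2.37-fold higher after DEP (1.28, SE 0.21, adjusted p = 4.02e-04), and GAPDH (0.67), ACTB (0.64), RACK1 (0.61), RPS18 (0.57) and RPLP1 (0.54) were higher as well. None of these 6 rises passed with the slide as a block, where GRM4 was at 0.60 (adjusted p = 0.193) and GAPDH at 0.41 (adjusted p = 0.118). The log2 signal of the 75th percentile was 9.26 to 9.54 in DEP, against 10.10 to 10.18 in PBS. The scaling may therefore make up much of these rises. Among control probes about as dim as GRM4, (+)E1A_r60_a22 and DCP_22_0 were higher than in PBS by 0.97 and 0.91. Mouse-GAPDH_5 and Rat-GAPDH_3 differed by -0.18 and -0.55. ACTB, RACK1, RPS18 and RPLP1 did not pass with quantile normalization, where ACTB and RPS18 had changes of 0.00, or with the percentile over all probes, or without the filter (adjusted p = 0.0703, 0.0627, 0.107 and 0.140). With the percentile over all probes EIF3D (-0.60), COX4I1 (-0.58) and ODC1 (-0.40) were lower as well; by the main fit EIF3D was at -0.21 (adjusted p = 0.130), and it passed as lower with median centring (adjusted p = 0.0488), normexp (adjusted p = 0.0371) and array weights (adjusted p = 0.0117). Relative to the median change of all probes, 0.14, GRM4 was higher by 1.14 and GAPDH by 0.53, while ACTG1 was at -1.51 and DYNLL1 at -1.22. In all, 6 reference genes were higher and 5 lower; adjusted over the list alone, 7 and 5.

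Probes ASHGA5P005879 and ASHGA5P030759 were at least 3.10-fold and at least 1.72-fold lower after DEP, and both passed with the slide as a block (adjusted p = 0.00168 and 3.49e-04). ASHGA5P044635 was at least 3.75-fold higher, but did not pass with the slide as a block (adjusted p = 0.972), and ASHGA5P027898 was at least 2.16-fold higher (adjusted p = 0.0549 with the block). In all, 4129 probes were higher and 1680 lower (5809, 40.7% of those tested), 2337 and 687 at 2-fold or more. The block left 928 higher and 1191 lower, and 1279 of the 5809 were called in the same direction. The percentage higher, 71.1%, was 54.0% with quantile normalization, 53.9% in the deposited value table, 88.9% with normexp and 36.9% with the percentile over all probes.

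**Figure D2:**
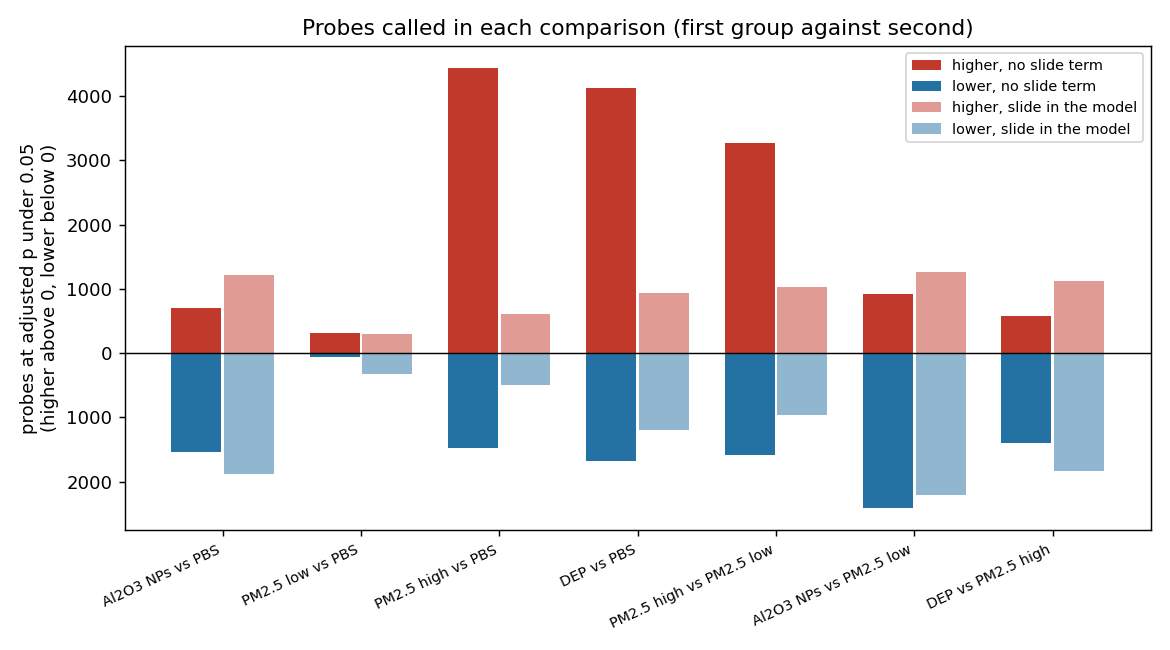
Number of probes called by limma at an adjusted p under 0.05 in each comparison, first group against second. Bars above 0 count higher probes and bars below 0 lower ones, dark without and pale with the slide in the model; the calls of PM2.5 high vs PBS drop from 4435 higher and 1474 lower to 604 and 493, while those of Al2O3 NPs vs PBS, on 1 slide, go from 709 and 1535 to 1220 and 1887.

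PM2.5 high against PM2.5 low compares 500 with 100 µg/ml. GAPDH was 3.01-fold higher at the high dose (log2 change 1.59, SE 0.11, adjusted p = 2.71e-06), and on slide 2 alone, where the 3 high-dose arrays met 1 low-dose array, its change was 1.41 (adjusted p = 0.00640). This gene lay above PBS at the high dose and below it at the low dose, the rise at the high dose without passing with the slide as a block. In all, 17 of the 18 reference genes were higher at the high dose, among them RPS18 (0.69), ACTB (0.68), GRM4 (0.66), PFN1, an actin-binding profilin (0.65), and ARHGDIA (0.65). In the fit with the slide as a block 5 of them passed, GAPDH (1.41), ARHGDIA (0.48), PRMT1 (0.45), EIF3D (0.45) and ODC1 (0.42), and on slide 2 alone ARHGDIA did not pass (0.48, adjusted p = 0.106). With quantile normalization RPS18, ACTB, GRM4 and PFN1 did not pass (0.06, 0.04, 0.44 and 0.09), nor without the filter (adjusted p = 0.0552, 0.0706, 0.112 and 0.0585). DYNLL1 did not pass (-0.02, adjusted p = 0.901). Adjusted over the list alone, the counts were the same, 17 and 0. The log2 signal of the 75th percentile was 9.24 to 9.31 in PM2.5 high and 9.57 to 10.07 in PM2.5 low. The scaling may therefore make up part of the 17 rises.

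ASHGA5P058274 was at least 3.09-fold higher at the high dose and ASHGA5P032351 at least 2.54-fold higher. ASHGA5P008172 was at least 3.07-fold and ASHGA5P027612 at least 2.51-fold lower. ASHGA5P032351 and ASHGA5P027612 did not pass on slide 2 alone, with its 1 low-dose array. Their log2 changes there were 3.575 and -3.15, against 3.66 and -2.91 on all arrays. The SE of these changes was 1.09 against 0.66 and 0.71 against 0.35. ASHGA5P008172 varied among the PM2.5 low arrays (level -2.93 ± 2.58, SD, n = 3) and did not pass with normexp (adjusted p = 0.141) or with only the groups compared (adjusted p = 0.0831). In all, 3260 probes were higher and 1588 lower, 1185 and 656 at 2-fold or more. The block gave 1033 higher and 963 lower, and slide 2 alone 429 and 416. Leaving out each array in turn gave 2770 calls (without PM2.5 low replicate 1) to 6065 (without PM2.5 low replicate 3). The lone PM2.5 low array there is assumed to vary like the arrays of the other groups. The percentage higher, 67.2%, was 52.0% with quantile normalization, 51.8% in the deposited value table, 89.6% with normexp and 41.8% with the percentile over all probes. Relative to the median change of all probes, 0.18, GAPDH was higher by 1.40.

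Al2O3 NPs against PM2.5 low compares 2 particles at 100 µg/ml. GAPDH was 3.26-fold higher after Al2O3 NPs (log2 change 1.70, SE 0.11, adjusted p = 6.18e-08; 1.79 with the slide as a block), and DYNLL1 was 2.05-fold lower (-1.03, SE 0.092, adjusted p = 1.50e-06). PRMT1 (-0.64), H3-3A (-0.61), EIF3D (-0.59) and COX4I1 (-0.56) were lower as well, and so were ODC1 and MTX1. The counts were 1 higher and 9 lower of 18, 1 and 10 adjusted over the list alone and 1 and 9 with the slide as a block. ACTG1, lower than in PBS after both, did not differ past the threshold between them (0.02, adjusted p = 0.895).

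ASHGA5P031802 was 32.6-fold lower after Al2O3 NPs than after PM2.5 low and ASHGA5P030215 was at least 13.8-fold lower, above background on 2 of the 3 Al2O3 NPs arrays. ASHGA5P008393, above background on 1 of the 3 PM2.5 low arrays, was at least 6.19-fold higher and ASHGA5P035565 at least 4.32-fold higher. In all, 917 probes were higher and 2413 lower (3330), 167 and 1093 at 2-fold or more. The block gave 1258 higher and 2206 lower, and on slide 1 alone, with 2 PM2.5 low arrays, 2055 and 2502. The percentage higher, 27.5%, was 40.6% with median centring and 42.8% with the percentile over all probes. Relative to the median change of all probes, -0.05, GAPDH was higher by 1.75.

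DEP against PM2.5 high was measured within slide 2, at doses of 50 and 500 µg/ml that are not matched. PRMT1 was 2.32-fold lower after DEP (log2 change -1.21, SE 0.10, adjusted p = 9.50e-07), DYNLL1 2.28-fold (-1.19, SE 0.092, adjusted p = 5.70e-07), ACTG1 2.24-fold (-1.16, SE 0.091, adjusted p = 6.12e-07) and MTX1 2.13-fold (-1.09, SE 0.088, adjusted p = 8.30e-07). EIF3D (-0.91), ODC1 (-0.80), H3-3A (-0.78), COX4I1 (-0.68) and ARHGDIA (-0.59) were also lower. GAPDH did not differ past the threshold (-0.13, adjusted p = 0.510). In all, 0 of the 18 were higher and 11 lower, with 12 lower adjusted over the list alone and 12 with the slide as a block. Among all probes 584 were higher and 1394 lower (1978), 183 and 625 at 2-fold or more. The fit with the slide as a block gave 1115 and 1829, and slide 2 alone 393 and 1230. The percentage higher, 29.5%, was 40.8% with median centring.

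**Figure D3:**
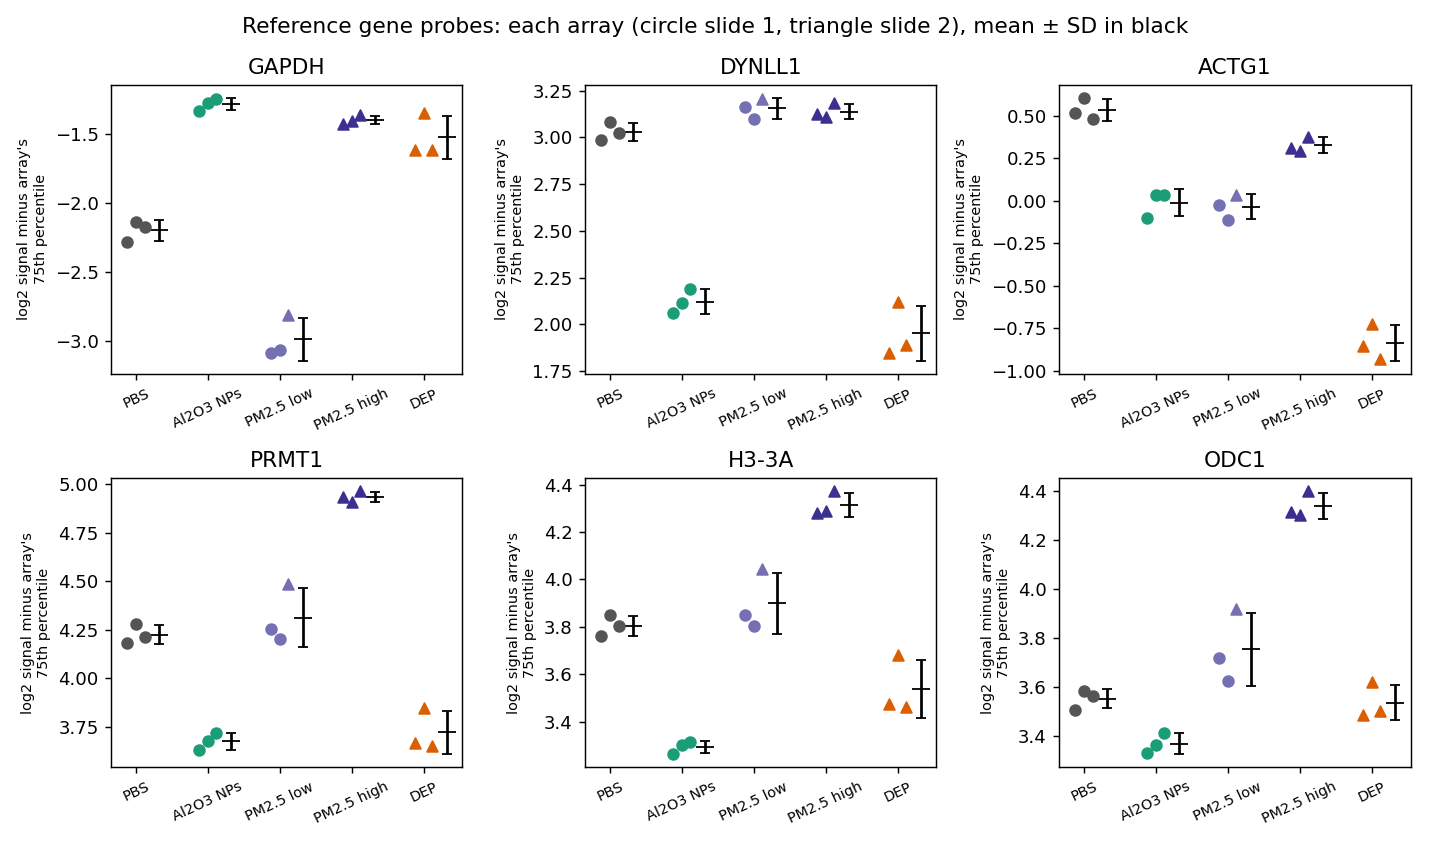
Levels of GAPDH, DYNLL1, ACTG1, PRMT1, H3-3A and ODC1 on each array, as log2 signal minus the array's 75th percentile, by group (n = 3 each; circles are slide 1, triangles slide 2, black bars the mean ± SD; each panel has its own axis). GAPDH lies above PBS after Al2O3 NPs (0.91 on the log2 scale) and below it after PM2.5 low (-0.79), and DYNLL1 lies below PBS after Al2O3 NPs (-0.91) and DEP (-1.08).

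The overlap of the 4 comparisons with PBS was then counted. DYNLL1, PRMT1, ACTG1 and H3-3A were lower after both Al2O3 NPs and DEP. GAPDH was higher after Al2O3 NPs, PM2.5 high and DEP, the last 2 without passing with the slide as a block. Al2O3 NPs and DEP shared 838 lower probes, against 181 for independent lists of those sizes, and 576 higher probes against 205, with 39 in opposite directions. PM2.5 high and DEP shared 3034 higher probes against 1282 and 543 lower probes against 173, with 194 opposite. Al2O3 NPs and PM2.5 high shared 551 higher probes against 220 and 215 lower probes against 158, with 401 opposite. With the slide as a block, Al2O3 NPs and DEP shared 773 lower and 292 higher probes with 36 opposite, PM2.5 high and DEP 376 and 389 with 18, and Al2O3 NPs and PM2.5 high 203 and 136 with 81.

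All 4 particle groups shared 155 higher and 9 lower probes, and 23 and 37 with the slide as a block. Across probes, which are not independent replicates, the changes of Al2O3 NPs and DEP correlated at 0.66, and those of PM2.5 high and DEP at 0.72. Simulated unchanged groups that shared 3 simulated PBS arrays gave 0.50 for both pairs. The other 4 of the 6 pairs lay below that value, at 0.17 for Al2O3 NPs and PM2.5 low, 0.37 for Al2O3 NPs and PM2.5 high, 0.38 for PM2.5 low and PM2.5 high and 0.36 for PM2.5 low and DEP. The covariances of the first 2 pairs were 0.315 and 0.438, against 0.0525 and 0.0527 simulated, and those of the other 4 were 0.0403, 0.160, 0.114 and 0.119, against 0.0521 to 0.0527. The 3 PBS arrays are too few to give each comparison at least 2 of its own, so part of the excess over independent lists may come from the shared controls. The simulated groups held no difference between slides. PM2.5 high and DEP both lay on slide 2 and PBS on slide 1. A slide difference may therefore also add to the overlap, correlation and covariance of PM2.5 high and DEP. In all, 4503 probes were called in the same direction in at least 2 of the 4 comparisons, and 1812 with the slide as a block.

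A pair of changes with no array in common and each within 1 slide was set side by side, Al2O3 NPs minus PBS on slide 1 and DEP minus PM2.5 high on slide 2. DYNLL1 changed by -0.91 and -1.19 in these, PRMT1 by -0.55 and -1.21, ACTG1 by -0.54 and -1.16, H3-3A by -0.51 and -0.78, COX4I1 by -0.49 and -0.68, and EIF3D by -0.48 and -0.91. In the fit of all 15 arrays these are the 6 genes that fell after Al2O3 NPs, and all 6 fell in DEP against PM2.5 high, where 3.67 would be shared by independent lists of 6 and 11 among 18; on slide 1 alone ARHGDIA, MTX1 and ODC1 were lower after Al2O3 NPs too (adjusted p = 0.0444, 0.0362 and 0.0311). ASHGA5P031802 changed by -3.43 and -3.62. Over 14244 probes the changes correlated at 0.453, and simulated unchanged groups gave -0.03 to 0.04. By the fits of each slide alone, both were lower for 851 probes against 189 for independent lists, both higher for 136 against 55.3, and 108 were opposite.

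**Figure D4:**
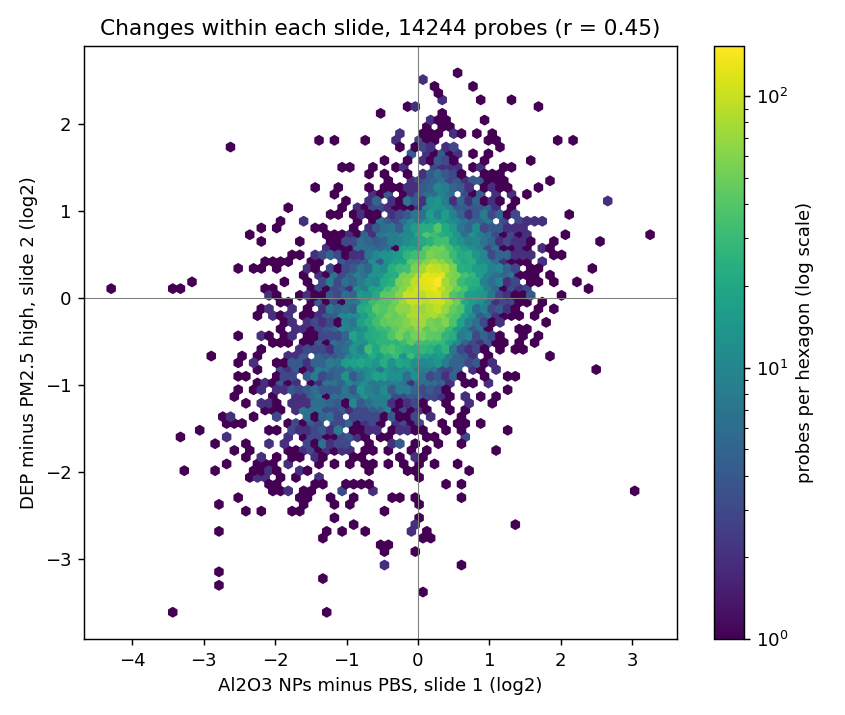
Log2 change of 14244 probes in Al2O3 NPs minus PBS on slide 1 (x axis) and in DEP minus PM2.5 high on slide 2 (y axis). Colour gives the number of probes in each hexagon on a log scale, the correlation across probes is 0.453, and ASHGA5P031802 lies at the lower left (-3.43 and -3.62).

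Over all 5 groups, 8861 of 14281 probes (62.0%) differed by the moderated F test, and 6015 with the slide as a block (any difference among the 5 groups). The other 3 of the 10 pairs of groups gave 5669 calls for DEP against PM2.5 low (3686 with the block), 3809 for DEP against Al2O3 NPs (1022 with the block) and 5422 for PM2.5 high against Al2O3 NPs (1890 with the block). ACTG1 was lower in DEP than in 2 other particle groups, at -0.82 against Al2O3 NPs (adjusted p = 4.71e-05; -0.93 with the block, adjusted p = 0.00158) and -0.80 against PM2.5 low (adjusted p = 3.01e-05). PRMT1 was at 1.26 in PM2.5 high against Al2O3 NPs (adjusted p = 3.23e-07, and 3.01e-04 with the block).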

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

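Tests chosen only after results were seen were the percentage of probes called between DEP and PM2.5 high on slide 2, the percentage of rises among dimmer and brighter calls and the splits within slides; slide 1 alone, slide 2 alone and the 75th percentile over all probes were added after the data were seen.

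Signals in the arrays' control spots, which no comparison used, were above background on all 3 arrays of an exposed group and on no PBS array. The control probe (+)E1A_r60_a107 was at least 1.35-fold higher in DEP than in PBS. The control probe DCP_22_4 was at least 1.33-fold higher in PM2.5 high and at least 1.17-fold higher in DEP, and DCP_22_7 at least 1.59-fold and at least 1.67-fold higher. Each of the 3 probes was also above background on 1 PM2.5 low array, and DCP_22_7 on 1 Al2O3 NPs array (at least 1.06-fold higher than in PBS). PM2.5 high and DEP lay on slide 2, and PBS and Al2O3 NPs on slide 1. Of the control probes above background on all 15 arrays, (+)E1A_r60_a22 was higher than in PBS by 1.006 in PM2.5 high and 0.97 in DEP (log2 scale). DCP_22_0 was higher by 0.93 and 0.91 and DCP_22_2 by 0.98 and 0.94. In Al2O3 NPs these 3 were higher by 0.38, 0.26 and 0.38. ERCC-00062_278 was lower in PM2.5 high and DEP, by 0.20 and 0.07, and higher by 0.25 in Al2O3 NPs. Mouse-GAPDH_3 differed from PBS by -0.0024 in PM2.5 high, -0.025 in DEP and 0.21 in Al2O3 NPs. In PM2.5 low, replicate 3, on slide 2, lay at -3.41 for (+)E1A_r60_a22, -3.47 for DCP_22_0 and -3.32 for DCP_22_2, above replicates 1 and 2, on slide 1, at -4.40 and -4.34, -4.19 and -4.26, and -4.49 and -4.36. All these levels are relative to the array's 75th percentile, which itself lay lower on slide 2. Its log2 signal was 10.10 to 10.18 in PBS, 9.24 to 9.31 in PM2.5 high and 9.26 to 9.54 in DEP. In PM2.5 low it was 9.57 in replicate 3 and 10.00 and 10.07 in replicates 1 and 2. A lower percentile raises the relative level of a probe whose signal is unchanged, so the scaling may make up much of these rises.

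The first pattern is the number of probes called in PM2.5 high and DEP against PBS: the difference of PM2.5 low replicate 3, on slide 2, from replicates 1 and 2, on slide 1, correlated across probes with the change in PM2.5 high at 0.482 and with that in DEP at 0.381, and it ran in the same direction as 81.0% and 72.2% of the calls. The difference of replicate 3 from replicate 1 correlated at -0.183 with the response of replicate 2. A stronger PM2.5 response of the same pattern in replicate 3 would give a positive value. Whatever replicates 1 and 2 share and replicate 3 lacks lowers that correlation, however. The changes of PM2.5 low and PM2.5 high correlated only at 0.38. These values therefore cannot tell a difference between slides from a response in replicate 3 closer to that of the high dose. The slides as the whole of both changes are argued against by the 11.4% of probes called between DEP and PM2.5 high within slide 2. A difference between slides may make up part of both changes, though a stronger response or a separate origin of replicate 3 stays open because 1 array joins the slides. The falls of ACTG1, DYNLL1, MTX1 and PRMT1 in DEP passed with the slide as a block, and an effect of the particles stays open for them.

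In the second pattern, rises outnumber falls in PM2.5 high and DEP against PBS: with the calls split at the median of the mean level of the 2 groups, the calls of PM2.5 high were 84.6% higher among the dimmer probes and 65.5% among the brighter ones, a difference of 19.1 percentage points, and those of DEP 77.7% and 64.4%, a difference of 13.3. Background of dim probes may add rises, as may another trend with signal, though rises outnumbered falls among the brighter probes too; the median local background was 26 to 28 on slide 2 and 30 to 40 on slide 1. The scaling also sets the balance, which was 37.9% higher for PM2.5 high vs PBS and 36.9% for DEP vs PBS with the percentile over all probes. The brightest reference probes, ACTB and RPLP1, rose by 0.85 and 0.73 in PM2.5 high and by 0.64 and 0.54 in DEP. The median change of all tested probes was 0.26 and 0.14. These values argue against a general rise of RNA relative to these probes. For other bright probes this was not tested.

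In the third pattern the changes of Al2O3 NPs and DEP go together. Shared control arrays and a difference between the slides are argued against by the correlation of 0.453 between Al2O3 NPs minus PBS and DEP minus PM2.5 high, which share no array. A trend with signal is argued against by 0.453 with both changes centred within 20 bins of mean signal. With PM2.5 low replicate 3 in place of PM2.5 high the correlation was 0.539, which rests on 1 array. That array was also exposed to PM2.5, so it cannot tell a change in DEP from one shared by both PM2.5 doses. A departure of PM2.5 in place of DEP therefore stays open. Of the 6 genes lower in both changes, H3-3A, COX4I1, PRMT1 and EIF3D were also higher in PM2.5 high than in PBS, across slides. DYNLL1 and ACTG1 were not higher past the threshold. A response common to both particles, with DYNLL1, PRMT1, ACTG1 and H3-3A lower than in PBS after each, was not tested on other data and stays open, as do cell number, RNA quality and order of handling, which are not in the labels.

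Other splits of the arrays were fitted in the same way. For each comparison of 3 with 3 arrays, 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real count and the highest of the others were 2244 and 13 for Al2O3 NPs vs PBS, 360 and 0 for PM2.5 low vs PBS, 5909 and 0 for PM2.5 high vs PBS, 5809 and 0 for DEP vs PBS, 4848 and 1 for PM2.5 high vs PM2.5 low, 3330 and 4 for Al2O3 NPs vs PM2.5 low, and 1978 and 14 for DEP vs PM2.5 high. For any difference among the 5 groups, 1 of 100 splits of the 15 arrays gave as many (8861, highest other 1798), and for the overlap of calls between particles 1 of 100 did (4503, highest other 1246). With arrays exchanged only within a slide, which keeps a difference between slides, again 1 of 100 splits gave as many of each (highest others 5732 and 3099). This argues against chance for these counts, and 1 of 100 is the lowest share that such splits can give. The splits take the arrays as exchangeable, and the labels do not state that the cultures were independent.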

How the results depend on the processing

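The alternatives slide 1 only, slide 2 only, the slide block with the filter on all 15 arrays, and the 75th percentile over all probes were chosen after the data were seen. Over all alternatives, the named genes and probes gave 1892 values. Of these, 1753 kept their side of the threshold and, where called, their direction, 110 lost the call, 24 gained one and 5 reversed. Direction was not compared for values called neither in the main fit nor in the alternative. Of 109 such values each, the slide as a block ended 28 calls and a further 1 that also reversed, and median centring ended 0. The 109 include values not called in the main fit and comparisons within 1 slide, so they understate the loss across slides. In PM2.5 high vs PBS, only ODC1 and ASHGA5P058274 of the named genes and probes kept a call with the block. No paired analysis was possible because the labels give no shared replicate numbers. The gene list and class alternatives were not run, for want of gene names. Signal over background limits the dim probes, since 24.2% of probes were bright enough to test. Except where stated, the cause was not tested.

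Counts more than 1.5 times from the main ones were as follows. Normexp gave 9646 for PM2.5 high vs PBS, 7798 for PM2.5 high vs PM2.5 low and 7207 for the overlap. No filter gave 1373 for Al2O3 NPs vs PBS, 159 for PM2.5 low vs PBS and 3135 for PM2.5 high vs PM2.5 low. Probes above background on all 15 arrays, which are fewer, gave 3320 for PM2.5 high vs PBS, 2767 for DEP vs PBS, 2966 for PM2.5 high vs PM2.5 low, 4857 for any difference and 2376 for the overlap. Array weights, 0.142 for PM2.5 low replicate 3 and 5.12 for replicate 1, gave 3617 for Al2O3 NPs vs PBS, 2587 for PM2.5 low vs PBS, 8937 for PM2.5 high vs PM2.5 low, 5660 for Al2O3 NPs vs PM2.5 low and 3118 for DEP vs PM2.5 high. The slide as a block gave 630 for PM2.5 low vs PBS, 1097 for PM2.5 high vs PBS, 2119 for DEP vs PBS, 1996 for PM2.5 high vs PM2.5 low and 1812 for the overlap. The block with the filter on all 15 arrays gave 667, 1203, 1990, 1872 and 1744 for these, and 4304 for any difference. Slide 1 only gave 4203 for Al2O3 NPs vs PBS and 932 for PM2.5 low vs PBS, and slide 2 only 845 for PM2.5 high vs PM2.5 low. Only the groups compared, with fewer arrays, gave 3807 for Al2O3 NPs vs PBS, 6 for PM2.5 low vs PBS and 2149 for Al2O3 NPs vs PM2.5 low. A log2 change of at least 1, a stricter rule, gave 856 for Al2O3 NPs vs PBS, 90 for PM2.5 low vs PBS, 2692 for PM2.5 high vs PBS, 3024 for DEP vs PBS, 1841 for PM2.5 high vs PM2.5 low, 1260 for Al2O3 NPs vs PM2.5 low and 808 for DEP vs PM2.5 high.

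Leaving out each array in turn gave 121 to 631 calls for PM2.5 low vs PBS, with 121, 129 and 124 without PBS replicates 1, 2 and 3 and 631 without PM2.5 low replicate 3. It gave 2770 to 6065 for PM2.5 high vs PM2.5 low, with 2770 without PM2.5 low replicate 1, 2941 without PM2.5 high replicate 1 and 3076 without PM2.5 high replicate 3. The ranges were 1592 to 1853 for Al2O3 NPs vs PBS, 4413 to 4966 for PM2.5 high vs PBS, 4770 to 5851 for DEP vs PBS, 2541 to 3456 for Al2O3 NPs vs PM2.5 low and 1386 to 2442 for DEP vs PM2.5 high. Quantile normalization reversed RPS18 in PM2.5 high vs PBS (-3.61e-05) and ACTB (-2.29e-06) and RPS18 (-1.30e-05) in DEP vs PBS, since it ties the brightest probes across arrays. The block reversed ASHGA5P044635 in DEP vs PBS (-0.10), a probe above background on no PBS array. The 75th percentile over all probes reversed DYNLL1 in PM2.5 high vs PBS (-0.27).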

Other observations

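The arrays carry a second set of probes for GAPDH and PGK1 among their control spots, which were not tested. The control probe Human-GAPDH_3 lay at -1.85 ± 0.029 in PBS, -1.18 ± 0.054 in Al2O3 NPs, -2.35 ± 0.064 in PM2.5 low, -1.35 ± 0.023 in PM2.5 high and -1.47 ± 0.13 in DEP on the log2 scale (SD, n = 3 each). Its differences from PBS were 0.68, -0.50, 0.51 and 0.38, in the same directions as those of the reference probe of GAPDH (0.91, -0.79, 0.80 and 0.67). The control probe Mouse-GAPDH_3, brighter at -0.12 in PBS, differed from PBS by 0.21, -0.15, -0.0024 and -0.025. It thus did not share the rises in PM2.5 high and DEP. Human-PGK1_3, a control probe for the glycolytic enzyme PGK1, differed from PBS by 0.62 in Al2O3 NPs, -0.11 in PM2.5 low, 0.03 in PM2.5 high and -0.42 in DEP. Human-GAPDH_5 and Human-PGK1_5 were above background on 0 arrays.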
